A study of Rattus norvegicus with 8 samples.

How the data were processed

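Total RNA of granulosa cells was extracted with a column kit, labelled with biotin and hybridised to Affymetrix whole-genome rat arrays, 1 array per sample, per the labels. The deposited table held 31099 probe sets on 8 arrays, of which 57 were controls. Its values are signal intensity on a linear scale, which the authors made with MAS5 per the submitters' processing notes, and the version is not given in the sources used here. The mean after trimming 2% at each end lay between 1500.5 and 1500.6 on every array, so each array had been scaled to a common mean before deposit. MAS5 summarises each array by itself and gives noisy values at low signal. No detection calls were used here, so probe sets near background were recognised from their rank on the array alone.

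Deposited signals were put on the log2 scale and each array was scaled to the common median of the probe sets above their array's median on all 8 arrays. A value under the array's 40th percentile was set to that percentile, called the floor. A gene counted as measured when its probe set lay above the array's median on at least 2 arrays. Of the probe sets, 20832 had 1 gene symbol, of which 6 were controls and were left out, and 436 had several and were left out, while 9780 were not listed in the platform annotation and stayed unnamed. The annotation can be old. Symbols were looked up by gene identifier in a gene table of the GRCr8 assembly, which held 20764 of them and changed 0. That table was used for names only, and no coordinates are given. The brightest probe set stood for a gene, which left 10513 measured of 14218 named genes. For the 2664 genes with more than 1 measured probe set, the log2 inner ranges of the brightest 2 differed by a median of 0.34. Signals are printed after scaling and before the floor, and ranges are taken after the floor. Signal levels served to choose a gene's brightest probe set and to match random lists, and no order of abundance between genes was drawn from them.

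All 8 arrays were left without a group, since the labels gave none, and nothing was inferred from label numbers, order or values. No group means, errors or tests between groups were computed. The spread of a gene was its log2 inner range, the second highest minus the second lowest array, which leaves out the single highest and lowest array. For 18 functional and 10 cell type lists, a list's score on an array was the mean over its measured members of the value minus the gene's median over arrays. The inner range of the score was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and the share at least as wide was adjusted by the Benjamini-Hochberg method over the 27 lists with at least 3 members. A list was called wide at an adjusted share under 0.05. This describes these arrays and is no test of a treatment. Relations between scores were to be given only for pairs of wide lists, and 1 wide list leaves 0 pairs. The step was also run on these arrays, against fewer random lists than above, with a shared shift added to lists of 17 genes drawn at random from the 10513. A log2 difference of 0.5 between 4 and 4 arrays was called in 13 of 20 such lists and a difference of 0.3 in 0 of 20. In each run 0 of 20 unshifted random lists were called, but these were random draws like the lists they were set against, so few calls were given by construction. The adjustment there covered 20 shifted and 20 unshifted lists, which is more lenient than where few lists are wide, so the 13 can overstate detection. Shared differences of these sizes or smaller can therefore have been missed.

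The lists, the design, the named genes and most alternatives were chosen before the data were examined. Named are the 15 genes with the largest inner range, up to 3 members of each list with the largest inner range and the 1 with the smallest, and Cyp19a1, Fshr, Inha, Foxl2, Amh, Cyp11a1, Star, Lhcgr, Cyp17a1, Igfbp5, Fas, Actb and Gapdh. Hsd17b1 was named outside that rule, to complete a count, after its value was seen, as were Lck, Gja1 and Eln and the genes named as widest over arrays 2194 to 2199. The matching of listed symbols through older names was corrected after first results had been seen, because it had put another gene in place of Cdh1. The stricter rule adopted then never reads a current symbol as an older name. It also took Hba-a3 out of the erythroid list, and the looser rule was kept as an added alternative.

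Alternatives were no scaling, quantile normalization, a floor at the 25th percentile or none, a filter on all 8 arrays or none, the mean of a gene's probe sets, the full range, the median of members, Spearman in place of Pearson correlation, and leaving out each array in turn. Added after seeing the data were arrays 2194 to 2199 alone, these without array 2195, relations between scores over arrays 2194 to 2199, and the looser matching of names. An array that lay far from the other 7 was found with Dixon's ratio at 0.526, the 95% critical value for 8 values. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.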

Results

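RNA of rat ovarian granulosa cells, the somatic cells that surround the oocyte and make oestradiol, was measured on 8 one-colour Affymetrix arrays of the whole rat genome. Per the series' design text, immature rats received eCG, a gonadotropin that stimulates follicle growth, and 24 h later either an antibody against eCG or pre-immune serum. The antibody drove follicles into atresia, the degeneration of the follicle, and 0% of the oocytes of that group developed to term. In the serum group 30 to 50% did. The labels of the 8 arrays differed only in a number, and no array could be placed in either treatment group. No comparison between the groups was therefore made. What follows gives the value on each array and the spread over arrays, and the number of arrays limits the precision. Arrays are named by their label number, and series of values run in the order 2074, 2076, 2194, 2195, 2196, 2197, 2198 and 2199.

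Genes of follicle endocrine function differed widely in how much they varied. Cyp19a1, the aromatase that makes oestradiol, gave scaled signals of 6422, 987, 11168, 15060.4, 3582, 10318, 20564 and 12760.4. Its inner range, the ratio of the second highest to the second lowest array, was 4.20-fold, larger than in 99.4% of genes of like signal. The full range was 20.8-fold. Its next brightest probe set had a smaller log2 inner range, 0.93 against 2.07, so the size depended on the probe set. Lhcgr, the receptor for luteinizing hormone, had an inner range of 3.67-fold, with 1008 on array 2076 and 753 on array 2196 against 1726 to 3729 on the other 6 arrays. Inha, the inhibin alpha subunit, had an inner range of 2.33-fold and a full range of 3.39-fold, from 26724 on array 2197 to 90530.1 on array 2074. Cyp11a1, which makes pregnenolone from cholesterol, had the smallest inner range of these, 1.24-fold around a median of 149232. Its full range was 1.93-fold, from 117741 on array 2194 to 227783 on array 2195. Star, which carries cholesterol into mitochondria, had an inner range of 1.57-fold and a full range of 1.63-fold, from 45984 to 74799.9, but its next probe set had a larger log2 inner range, 1.17 against 0.65. The granulosa transcription factor Foxl2 had an inner range of 1.85-fold and a median of 6521. Without array 2076 or 2196 the inner range of Cyp19a1 was 2.34-fold and that of Lhcgr 2.16-fold. Amh, a hormone of small growing follicles, ran from 242 on array 2199 to 1057 on array 2076 (inner range 2.43-fold) and was at the floor on 1 array. Igfbp5, a binding protein linked to atresia, lay between 3476 and 6102 on 7 arrays and at 11116 on array 2199. The death receptor Fas (inner range at least 1.86-fold, at the floor on 3 arrays) and the androgen-making enzyme Cyp17a1 (at least 2.24-fold, at the floor on 5 arrays) were too weak for their order over arrays to be read. No probe set with a single gene name was listed for Fshr or Actb, and for Gapdh only control probe sets were, which were left out and of which the 3' one had deposited signals of 36037 to 74940.3.

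**Figure D1:**
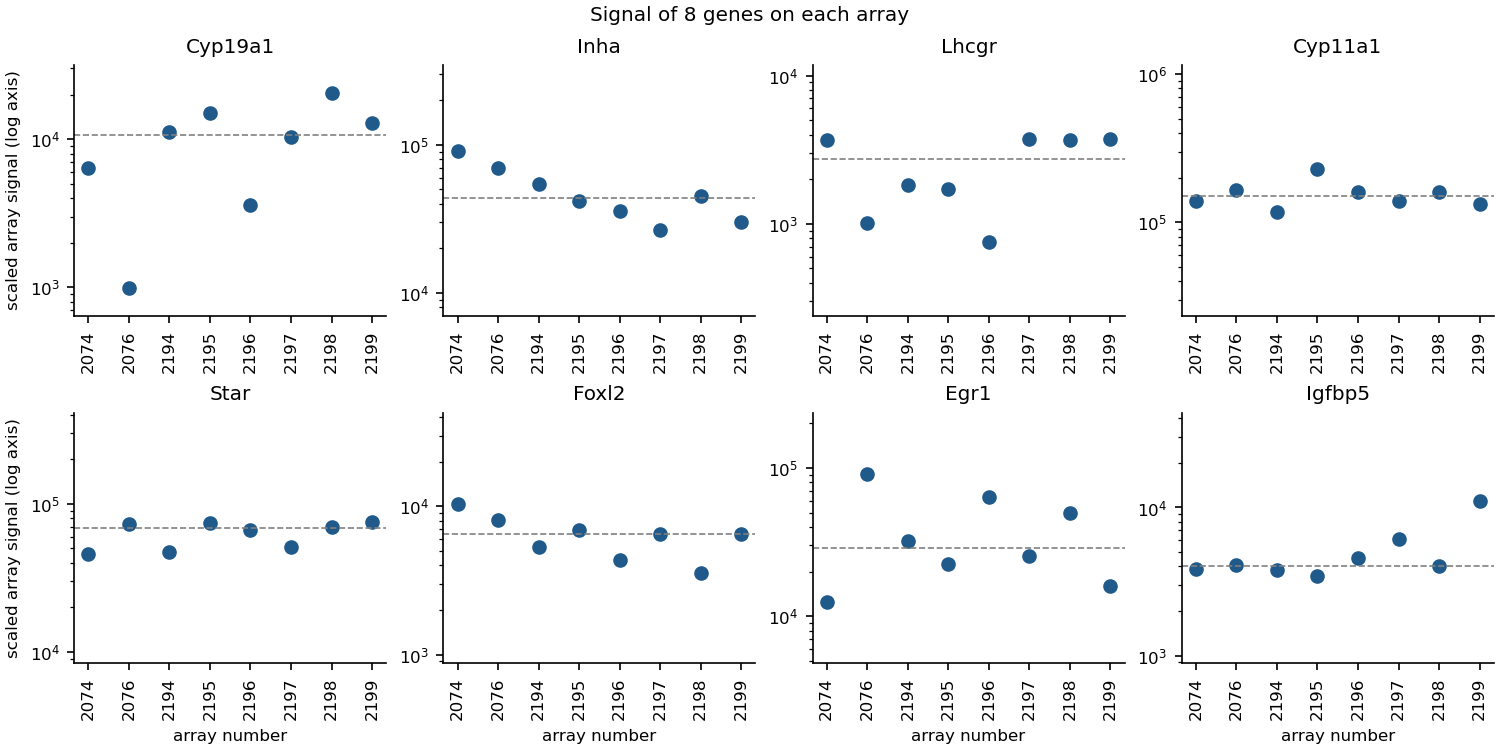
Scaled signal of 8 genes (log axis, array intensity) on each of the 8 arrays, 1 point per array, with the gene's median over arrays as a dashed line and the same span of the axis in each panel. Cyp19a1 ranged from 987 to 20564, whereas Star stayed between 45984 and 74799.9.

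Across the 10513 genes measured, the median log2 inner range was 0.78, or 1.71-fold, and the 95th percentile was 1.60, or 3.02-fold. An inner range of at least 2-fold was found for 3130 genes and of at least 4-fold for 136 genes. Values under the floor were raised to it, and the floor ran from 273 to 471 over arrays, highest on array 2195. Where a raised value could move the second lowest rank, the inner range is a lower bound, given as "at least", which held for 2433 genes, 297 of them with 1 array at the floor. In 142 of the 2433 the second highest value had been raised too, so there the inner range is no strict lower bound. None of the 142 had an inner range of at least 2-fold. Of the genes under 2-fold, 1244 were among the 2433, these 142 included. The 15 genes with the widest inner range were Mis18a (12.7-fold), Rsu1 (11.3-fold), Adamts4 (9.89-fold), Fkbp8, Csf1, Tcim, Zng1a, Gbx2, Arf5, Zhx2, Osbpl5, Nudcd2, Hyou1, Kcne2 and Angel2 (6.72-fold). Adamts4, a protease of the extracellular matrix, gave 1706 on array 2074 and 1384 on array 2076 and 3910 to 18852 on the other 6. Nudcd2 gave 2231 and 2312 on that pair and 14454 to 16948 on the other 6. In 13 of the 15 genes arrays 2074 and 2076 both lay beyond the other 6 arrays, below them in 10 and above in 3. The next brightest probe set had a log2 inner range of 0.73 for Csf1, at least 0.56 for Angel2 and at least 0.61 for Kcne2. Gbx2 and Kcne2 were each at the floor on 3 arrays and Fkbp8 on 1, and the inner ranges of these 3 genes are lower bounds. Leaving out 1 array changed the inner range by over 1.5 times in 44 of the 123 named genes, in 32 of them when the array was 2074 or 2076, and the values without the array are given with each group of genes. All of the 15 widest genes were among the 44. Without array 2074 or 2076 the inner range was 1.16-fold in Nudcd2, 1.21-fold in Osbpl5, 1.53-fold in Zng1a, 2.50-fold in Rsu1, 2.85-fold in Hyou1, 3.19-fold in Arf5, 4.22-fold in Tcim, 4.30-fold in Adamts4, at least 4.76-fold in Fkbp8 and 6.99 to 7.002-fold in Mis18a. It was 1.68-fold in Angel2 without array 2198 or 2199, 2.78 to 2.79-fold in Csf1 without 2195 or 2198, at least 3.32-fold in Gbx2 without 2197 or 2198 and 4.71 to 4.72-fold in Zhx2 without 2194 or 2198. Mis18a also had 4.90-fold without array 2196 or 2199, Hyou1 4.47-fold without 2196 or 2197, Fkbp8 5.58 to 5.59-fold without 2198 or 2199 and Adamts4 6.05-fold without 2195 and 5.97-fold without 2198. Without array 2195 or 2196 another probe set stood for Kcne2, with 1.54-fold and at least 1.39-fold. The counts fell when arrays were left out, which narrows an inner range by construction. At least 2-fold was reached by 1937 genes without array 2074 and also by 1937 without array 2076, by 1210 over arrays 2194 to 2199 alone, against 1063 to 1954 when any of the other 27 pairs was left out, and by 550 when array 2195 was left out as well. At least 4-fold was reached by 52 genes without array 2074, 55 without array 2076, 90 without array 2195, 30 over arrays 2194 to 2199 and 13 without all 3 arrays.

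Immediate-early genes, which are induced within minutes of a stimulus, formed the only 1 of 27 tested gene lists called wide with the primary settings (adjusted share under 0.05). Not being called wide does not show that a list's members did not vary together. Of the 26 other lists, 16 were called wide under at least 1 alternative setting and 10 under none. The list score, the mean log2 distance of its 19 measured members from their medians, was -0.41, 0.37, -0.09, 0.22, 0.25, -0.32, 0.32 and -0.31. Its inner range of 0.64 compared with a median of 0.21 among 10000 random lists, and the share of random lists at least as wide was 1e-04, the smallest obtainable (Benjamini-Hochberg adjusted share 0.0027). The transcription factor gene Egr1 gave 12421, 91057, 32103, 22513, 63868, 25274, 49469 and 16018, an inner range of 3.99-fold. Junb had an inner range of 3.33-fold and Nr4a3 of at least 3.02-fold, while Zfp36 had 1.43-fold. Without array 2074 another probe set stood for Nr4a3, with 1.63-fold. An inner range of at least 2-fold was found in 8 of the 19 members. The list was wide under 20 of 21 alternatives. Without the floor on low signals the score inner range was 0.59 and the median of random lists 0.27, and at an adjusted share of 0.0958 the list was not called wide. With genes required above the median on all 8 arrays it was 0.57 over 15 members and still wide (random median 0.19, adjusted share 0.013). The number of lists called wide rose from 1 to 5 without array 2074, to 6 without array 2076, to 2 without array 2194, 2195, 2196 or 2197 in turn, to 7 over arrays 2194 to 2199 and to 6 when array 2195 was also left out. Before adjustment 8 of the 27 lists had a share under 0.05.

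None of the 4 lists on ovulation, steroid output and follicle growth was called wide with the primary settings, and each was under at least 1 alternative. The ovulation and luteinization list had a score inner range of 0.55 (17 members measured, adjusted share 0.0607), from -0.47 on array 2199 to 0.60 on array 2198. It was wide under 15 of 21 alternatives (adjusted shares 0.00125 to 0.158), among them no scaling (0.027), quantile normalization (0.0229), genes required on all 8 arrays (0.013) and 6 of the 8 that left out 1 array. In 10 of its 17 members the inner range was at least 2-fold, with Sult1e1, an oestrogen sulfotransferase, at 3.43-fold, Edn2, a vasoconstrictor peptide, at 2.87-fold and Adcyap1 at 2.85-fold, and Cdkn1b at 1.53-fold (log2 inner range 0.62, and 0.97 in its next probe set). Without array 2076 or 2194 Edn2 had 1.84-fold. Cholesterol synthesis and uptake had 0.49 (17 members, adjusted share 0.154). There Mvd, an enzyme of the mevalonate pathway, had a log2 inner range of 2.58, Srebf2 an inner range of 2.56-fold and Mvk of 2.43-fold, while Msmo1 had 1.22-fold. The list was wide under 9 of 21 alternatives (0.0025 to 0.228), among them no scaling (0.027), quantile normalization (0.0081) and leaving out array 2074 (0.00405) or 2076 (0.0045). Mvd had 3.65-fold without array 2074 or 2076 and 2.96-fold without 2194 or 2199, and Srebf2 had 1.56 to 1.57-fold without 2194 or 2198. Steroidogenesis had 0.36 (14 members, adjusted share 0.195). At least 2-fold was reached by 4 of them, which were Cyp19a1, Nr5a1 (3.14-fold), Scarb1 (2.71-fold) and Hsd17b1 (2.44-fold). Nr5a1 had 1.80 to 1.81-fold without array 2195 or 2198. The list was wide under 2 of 21 alternatives, both over arrays 2194 to 2199 (0.0343, and 0.0357 with looser matching of names), and shares reached 0.605. The next probe set of Scarb1 varied more, with a log2 inner range of 2.50 against 1.44. Gonadotropin-responsive follicle growth had 0.35 (18 members, adjusted share 0.195), with at least 2-fold in 10 members. Among these were Lhcgr, Gata6 at least 2.87-fold and the Kit ligand gene Kitlg at 2.73-fold, and Vcan had 1.21-fold. Their next probe sets differed, with log2 inner ranges of 0.70 against 1.45 for Kitlg and 0.85 against 0.27 for Vcan. Of 21 alternatives only the mean of probe sets made this list wide (0.0344, the others up to 0.959).

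Cell death and survival lists were not called wide with the primary settings either. The apoptosis-promoting list had a score inner range of 0.23, the same as the median of its random lists, and an adjusted share of 0.525 over 18 members, and it was wide under 0 of 21 alternatives. Foxo1, a transcription factor restrained by survival signals, had an inner range of 4.33-fold, with 12314 on array 2074 and 6311 on array 2076 against 1388 to 4019.9 on the other 6. With 1 of these 2 arrays left out it was 2.74-fold. Endog had at least 2.35-fold and Tnfrsf1a 2.07-fold, whereas Apaf1 had 1.15-fold, although its next probe set had a log2 inner range of at least 1.08. Survival and anti-apoptosis had 0.46 (13 members, adjusted share 0.158), with Rela at 3.46-fold, Birc2 at least 2.67-fold, Bag1 at 2.41-fold and Mcl1 at 1.39-fold. Rela gave 6226 and 7836 on arrays 2074 and 2076 and 1521 to 2981 on the other 6, and Bag1 gave 12823 and 13707 against 5162 to 7534. Without array 2074 or 2076 the inner range was 1.64 to 1.65-fold in Rela and 1.41 to 1.42-fold in Bag1. The list was wide under 4 of 21 alternatives (0.018 to 0.486), which were no scaling (0.0479), quantile normalization (0.0229), the mean of probe sets (0.0344) and the median of members (0.018). The follicle atresia-associated list had 0.34 (16 members, adjusted share 0.195). At least 2-fold was reached by 9 of its members, led by the lysosomal protease Ctsd at 4.41-fold, the matrix protein Mgp at 3.91-fold and Ctss at 2.96-fold, while Ctsl had 1.52-fold. Ctsd gave 5555 and 4814 on arrays 2074 and 2076 and 812 to 2098 on the other 6, and had 1.91-fold with 1 of these 2 arrays left out. The list was wide under 2 of 21 alternatives (0.0054 to 0.3296), the full range and genes required on all 8 arrays (0.049995).

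No growth or matrix list was called wide with the primary settings. The cell cycle list had a score inner range of 0.24 (28 members, adjusted share 0.268), and 23 of its 28 members stayed under 2-fold. Among 21 alternatives 1 made it wide, that without arrays 2074, 2076 and 2195 (0.0287, the others up to 0.382). Aurka had 2.36-fold, Plk1 2.33-fold and Ccne1 at least 2.22-fold, and Pcna had 1.08-fold around a median of 14259. Extracellular matrix and proteases had 0.33 (20 members, adjusted share 0.158), led by Adamts4, Plau at 3.11-fold and Plat, the tissue plasminogen activator, at 2.98-fold, with Lamc1 at 1.18-fold (log2 inner range 0.24, but at least 1.36 in its next probe set). It was wide under 5 of 21 alternatives (0.0081 to 0.407), among them leaving out array 2074 (0.0427) or 2076 (0.0414). The TGF-beta and Wnt lists were wide under none. TGF-beta and BMP signalling had 0.19 (22 members, adjusted share 0.503). Its member Inhba had 2.72-fold, Tgfbr3 at least 2.48-fold and Amh 2.43-fold, and Smad3 had 1.11-fold. Wnt signalling had 0.47 (13 members, adjusted share 0.287), with Wnt4 at 3.22-fold, Sfrp4 at least 2.75-fold (at the floor on 5 arrays) and Axin2 at least 2.72-fold (on 4), and Sfrp1 at least 1.43-fold. Inhba had 1.66-fold without array 2076 or 2196, Wnt4 1.49-fold without 2074 and 1.496-fold without 2076, and Sfrp4 at least 1.72-fold without 2194 or 2195.

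Stress and metabolism lists were likewise not called wide with the primary settings. Glycolysis and hypoxia had a score inner range of 0.41 (19 members, adjusted share 0.158), with Pfkl at 3.50-fold, Pfkfb3 at 3.14-fold, Ddit4 at a log2 inner range of 1.59 and Pfkp at 1.27-fold. This list was wide under 2 of 21 alternatives (0.0027 to 0.5997), the full range and quantile normalization (0.0281). Without array 2074 or 2076 Pfkfb3 had 1.65-fold and Ddit4 1.52-fold. Antioxidant defence had 0.37 (18 members, adjusted share 0.158), with Gclm at 3.44-fold, Gsta1 at 3.20-fold, Gpx4 at 2.89-fold and Txnrd1 at 1.22-fold, although the next probe set of Txnrd1 had a log2 inner range of at least 1.44 against 0.29. It was wide under 2 of 21 alternatives (0.0263 to 0.397), the mean of probe sets and leaving out array 2076. Gpx4 had 1.47-fold without array 2074 or 2076, and Gclm 2.13-fold without 2196 and 2.11-fold without 2198. Endoplasmic reticulum stress had 0.27 (17 members, adjusted share 0.352), with Trib3 at 2.40-fold, Pdia4 at 2.38-fold, Dnajb9 at 2.27-fold and Herpud1 at 1.20-fold. Heat shock had 0.39 (10 members, adjusted share 0.253). In that list Hspa1a had 4.54-fold, Hspb1 3.34-fold and Hspa4 2.52-fold, and Hspd1 had 1.14-fold. Hspa1a had 2.32-fold without array 2197 or 2198. The list was wide under 3 of 21 alternatives (0.0075 to 0.932), over arrays 2194 to 2199, with looser matching as well, and without arrays 2074, 2076 and 2195 (0.0075). Interferon response had 0.38 (11 members, adjusted share 0.449), with Psmb9 at 3.27-fold, Oasl at 3.14-fold, Psmb8 at 2.43-fold and Irf1 at 1.66-fold. Psmb8 had 1.28-fold without array 2074 or 2076, Psmb9 2.14-fold without 2196 or 2197, and Oasl 1.91-fold without 2074 and 1.92-fold without 2197. The reference genes had 0.36 (10 members, adjusted share 0.29), with at least 2-fold only in Rplp0 (2.16-fold). Rplp0 gave 29115 and 25796 on arrays 2074 and 2076 against 10909 to 16597 on the other 6, and had 1.38-fold with 1 of these 2 arrays left out. The endoplasmic reticulum stress, interferon and reference lists were wide under 0 of 21 alternatives. Pgk1 had 1.73-fold, B2m 1.71-fold and Hprt1 1.22-fold.

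**Figure D2:**
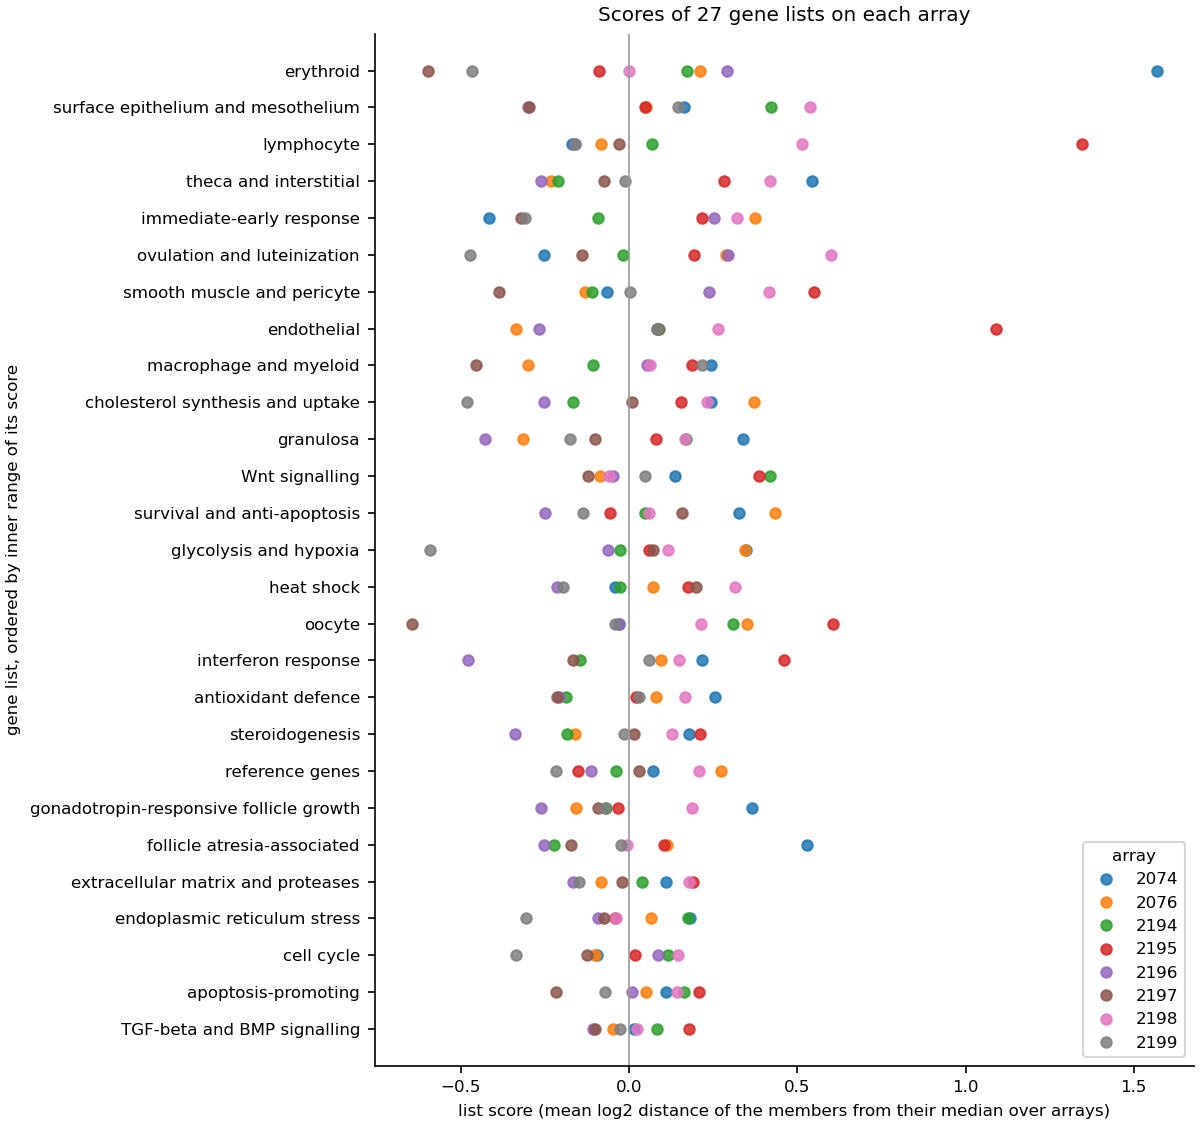
Scores of the 27 tested gene lists (mean log2 distance of the members from their medians over arrays), 1 point per array, lists ordered by the inner range of the score. Immediate-early response, at 0.64, was the only list called wide with the primary settings, and lists with wider scores, such as lymphocyte at 0.68, had 3 to 9 measured members.

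Cell type markers were scored the same way. The granulosa list had a score inner range of 0.48 (13 members, adjusted share 0.158), and 12 of its 13 members lay above the array median on all 8 arrays. It was wide under 6 of 21 alternatives (0.0081 to 0.344), among them leaving out array 2074 (0.0081) and genes required on all 8 arrays (0.0387). Its scores were 0.34, -0.32, 0.17, 0.08, -0.43, -0.10, 0.17 and -0.18. Theca and interstitial markers had 0.65 (9 members, adjusted share 0.158), with Col3a1 at 3.82-fold, Lhcgr at 3.67-fold, Col1a2 at 2.40-fold and Dcn at a log2 inner range of at least 0.53 (0.59 with the second highest value raised to a floor), and 2 members above the array median on all arrays. It was wide under 2 of 20 alternatives (0.025 to 0.676), the mean of probe sets and leaving out array 2076 (0.0319). Col3a1 had 2.44-fold without array 2074, 2.42-fold without 2195 and 2.21-fold without 2196 or 2199, and Col1a2 had 1.60-fold without 2074 or 2076. The macrophage and myeloid list had 0.52 (13 members, adjusted share 0.255), with Csf1r at 3.33-fold, Mrc1 at least 3.25-fold and C1qc at least 2.70-fold, and Cd14 at 1.60-fold. Csf1r had 1.99-fold without array 2074 and 1.997-fold without 2076, and C1qc at least 1.76-fold without 2074 or 2195. The erythroid list had 0.76 (3 members, adjusted share 0.275). Its member Hbb, a haemoglobin chain, gave 45704 on array 2074 and 3709 to 12573 on the other 7. Of 18 alternatives the full range (0.0054) and looser matching over arrays 2194 to 2199 (0.038) made the list wide, and shares reached 0.764. The remaining lists rested on 6 or fewer measured members. With the full range, which rests on single arrays, the endothelial (0.0498) and lymphocyte (0.0412) lists were wide, under 1 of 20 alternatives each, and the macrophage, oocyte, smooth muscle and surface epithelium lists were wide under none. The oocyte list had 0.39 (3 members, adjusted share 0.875), with Gdf9 at 2.51-fold, Zp2 at least 2.49-fold and Ooep at 1.13-fold. Without array 2076 Gdf9 had 1.496-fold and without 2195 1.48-fold. Endothelial markers had 0.53 (6 members, adjusted share 0.472), with Tek at least 3.07-fold, Tie1 at least 2.33-fold, Egfl7 at 1.93-fold and Emcn at least 1.78-fold. Lymphocyte markers had 0.68 (6 members, adjusted share 0.288), with Cd2 at least 2.52-fold, Il2rb at least 2.38-fold, Cd3d at least 2.19-fold and Cd3g at least 1.38-fold. Cd2 was at the floor on 6 arrays, Cd3d on 3 and the others on 2. Smooth muscle and pericyte markers had 0.55 (4 members, adjusted share 0.52), with Pdgfrb at least 2.62-fold, Myh11 at least 2.20-fold, Acta2 at 1.69-fold and Cnn1 at least 1.53-fold. Pdgfrb had at least 1.56-fold without array 2195 or 2199. Surface epithelium and mesothelium markers had 0.72 (3 members, adjusted share 0.442), with Msln at least 2.25-fold, Krt8 at least 1.75-fold and Wt1 at 1.44-fold. Adipocyte markers had only 2 measured members, Lpl at least 1.88-fold and Plin1 at least 1.59-fold, and were not scored.

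The arrays differed in quality measures. The correlation of each array with the median of the other 7, across genes, which are not independent replicates, was 0.936, 0.943, 0.965, 0.930, 0.969, 0.967, 0.953 and 0.957. The ratio of 3' to 5' signal of the beta-actin control probe sets, which rises as RNA or its copies get shorter, was 10.99 on array 2074 and 12.1 on array 2076, against 4.67 to 8.08 on the other 6. The 3' signal itself was highest on that pair, at 68066 and 75260 against 16465 to 36995, so the ratio alone does not show shorter RNA there. The GAPDH ratio ran from 5.27 to 8.81 and did not set that pair apart, although its 3' signal was highest there too, at 74940.3 and 64384 against 36037 to 60302. Array 2195 had the highest deposited median signal, 648, against 396 to 525 on the other 7.

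**Figure D3:**
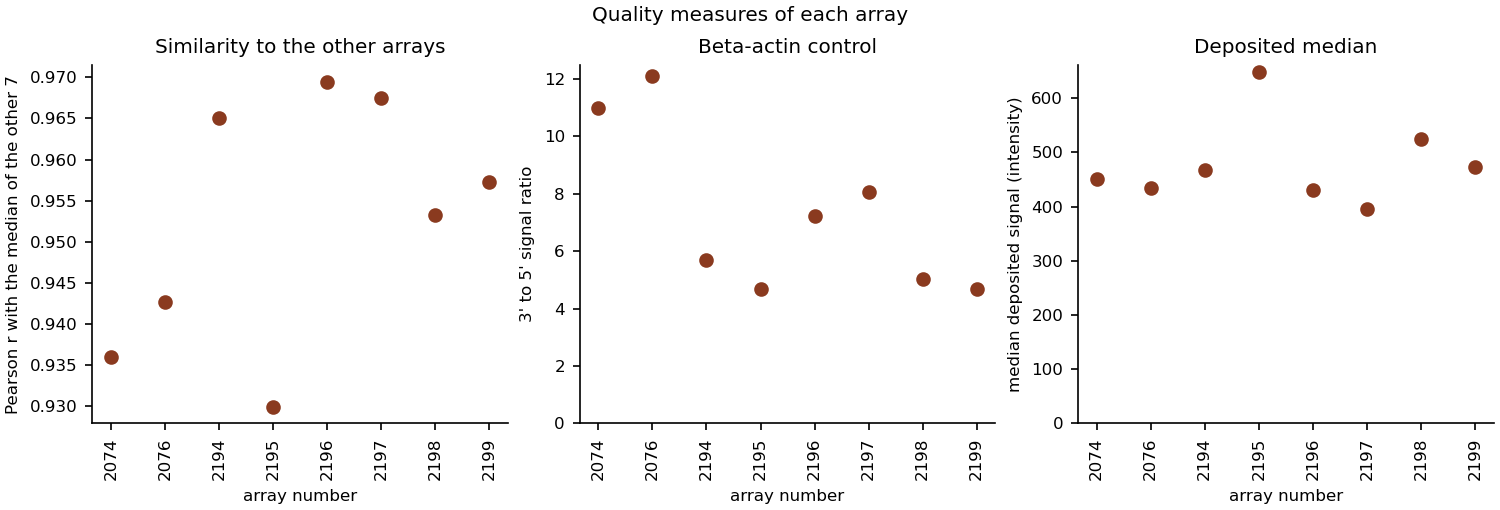
Pearson r of each array with the median of the other 7 arrays, 3' to 5' signal ratio of the beta-actin control and median deposited signal (intensity), 1 point per array. Arrays 2074 and 2076 had the highest beta-actin ratios, 10.99 and 12.1, and array 2195 had the highest median, 648.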

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

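The tests of labelling and of other cell types for arrays 2074 and 2076 were chosen after the result was seen, as was the set of the other 27 pairs used beside the test of single probe sets. In 15 of 164 values examined, 1 array lay farther from the others than Dixon's ratio allows at the 95% level, and chance alone gives about 1 in 20. The ratios were taken after the floor, which shortens the range of weak genes and so raises the ratio. The calls of Slc4a1 (at the floor on 4 arrays), Cd3g (on 2) and Alas2 (on 2) rest on it. Their lowest signals before the floor were 26.6, 58.6 and 88.3. List scores were taken after the floor as well. The erythroid call on array 2074 depends on it, since Slc4a1, 1 of 3 members, was raised there from 26.6. Endothelial and lymphocyte members were at the floor on up to 5 (Tie1) and 6 (Cd2) arrays, so the calls of these lists can rest on it too. Array 2195 was the distant one in 6 of the 15 and array 2074 in 4.

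Endothelial and lymphocyte markers were highest on array 2195, with list scores of 1.09 and 1.35 against at most 0.26 and 0.52 on another array. All 6 measured lymphocyte markers and 4 of 6 endothelial ones were highest there, with Lck at 2070.3 (median of the other 7 arrays 786) and Egfl7 at 1562 (median 673). The endothelial marker Esam, at the floor on no array, went the other way, at 713 (median 982). None of the 12 is in another list, and only 1 in each list lay above the array median on all arrays. Weaker sample signal over background is a candidate explanation: genes in the lowest 5 of 20 bins by signal were shifted by a median of 0.46 (log2) on array 2195 and by at most 0.16 on another, and all 18 hybridization control probe sets, which are added in fixed amounts, were brightest there, by 1.58 to 2.04 times the next array. Against random lists of like signal on that array the 2 lists lay at percentiles 98.8 and 99.8, and the other cell type lists at 5.83 to 66.62. The 2 lists had been picked for their high scores on that array, so these percentiles cannot decide the question. Additional endothelial and lymphoid RNA remains open, no sort or gate being stated, and no biological explanation could be tested without groups.

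On array 2195 the 3' to 5' ratio of the spike-in LysX was 22.3 against 11.9 on the next array, and the hybridization control cre gave 658594 against 348937. Cd3g had a log2 signal of 10.04 there and Hspd1 of 18.11. On array 2074 the follicle atresia-associated score was 0.53 against 0.11 on the next array, the erythroid score was 1.57 against 0.29, and log2 signals were 11.64 for Alas2, which makes haem in red cells, and 13.69, the lowest, for Mcl1. Of the 3 erythroid members, Hbb and Alas2 were highest on array 2074, but Slc4a1 was lowest there, at 26.6 (median 304). The floor of 302 raised that value, so the size of the erythroid score depends on the floor. The glycolysis and hypoxia score was -0.59 on array 2199, against -0.06 on the next array, and Txnrd1 was lowest there at 12.37 (log2). On array 2194 Nr5a2 was lowest at 14.85 and Slc4a1 highest at 9.83 (log2). Smad3 was lowest on array 2198 at 10.89 (log2).

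Arrays 2074 and 2076 lay apart from arrays 2194 to 2199. Both lay beyond the other 6 arrays in 27.4% of measured genes, against 7.14% by chance and at most 10.02% for any of the other 27 pairs of arrays. RNA from other cell types stays open: 2 of 49 markers of cell types other than granulosa, Hbb and Col1a2, lay above the other 6 on both arrays, and 0.905 of random lists of like signal had at least as many (median 4), but 0.254 had as few. A difference in labelling or array processing stays open too: 4 of 9 spike-in 3' to 5' ratios set the pair apart, but 7 did so for arrays 2195 and 2199. Of the 4, LysX, PheX and r2-lys were lower on the pair and ThrX was higher. The beta-actin ratio was higher there (10.99 and 12.1, against 4.67 to 8.08 on the other 6), so these controls did not all go one way. An effect on single probe sets cannot be told apart from one on transcripts. The next probe set went the same way in 58.8% of 905 genes (95% Wilson interval 55.5 to 61.9%) but in a median of 59.0% for the other pairs. In these genes, which were chosen by the brighter probe set, the median log2 difference was 0.78 in that probe set. Along the same direction it was 0.14 in the next one. A difference in treatment was not tested since no array has one.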

How the results depend on the processing

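The choices added after the data were seen are arrays 2194 to 2199 alone, these without array 2195, relations between scores over arrays 2194 to 2199, and the looser matching of names. Leaving out each array in turn was planned. Signal over background limits the counts: at least 4-fold was reached by 710 genes with a floor at the 25th percentile and 1199 with no floor, and the lowest correlation of an array with the others was 0.897 and 0.869. With no floor 0 lists were wide, and the immediate-early score inner range was 0.59 against a random median of 0.27 (adjusted share 0.0958, against 0.00125 to 0.0182 under the other settings). With genes required on all 8 arrays, 1306 genes reached 2-fold and 53 reached 4-fold, 4 lists were wide and the lowest correlation was 0.906. The full range, by construction wider, gave 7503 and 1385 genes and 9 wide lists. Lists called wide numbered 4 with no scaling, 5 with quantile normalization, 8 with the mean of probe sets and 3 with the median of members. Over arrays 2194 to 2199, 1210 genes reached 2-fold and 30 reached 4-fold, and 7 lists were wide, or 8 with looser matching, which added the erythroid list. Without arrays 2074, 2076 and 2195 the numbers were 550, 13 and 6, and the lowest correlation was 0.950. The lowest Spearman correlation was 0.899. Leaving out each array in turn gave 1937 to 2594 genes at 2-fold, 52 to 109 at 4-fold and 1 to 6 wide lists. The inner range falls by construction with fewer arrays, and the cause was not tested for the other changes. Of 2125 inner ranges of named genes under alternatives, 1672 moved by less than 0.34 (log2), the median difference between probe sets of a gene. Of 553 list calls, 494 kept their side of the threshold, 58 became wide and 1 was lost. No paired analysis was possible because no array has a group.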

Other observations

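Over arrays 2194 to 2199 alone, chosen after the data were seen by the run of label numbers, 7 lists were called wide: steroidogenesis (score inner range 0.30, adjusted share 0.0343), cholesterol synthesis and uptake (0.39, 0.0025), ovulation and luteinization (0.42, 0.0025), extracellular matrix and proteases (0.32, 0.0081), heat shock (0.40, 0.02), immediate-early response (0.52, 0.0025) and granulosa markers (0.34, 0.0246). The widest genes over these 6 arrays were Csf1 (8.96-fold), Angel2 (6.77-fold), Zhx2 (6.42-fold) and Vwa3a (6.32-fold), and 5 of the widest 15 were also among the widest 15 over all 8 arrays. Eln, the elastin gene, gave 2198 on array 2198 and 2060.4 on array 2199 against 252 to 685 on the other 4.

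Of the 21 pairs of these 7 lists, 14 could be related over the 6 arrays, and 7 were left out because a score had a gap. The relations were tested after the data were seen. None had an adjusted p under 0.05 by exact permutation (lowest 0.175), and 3 had an unadjusted p under it. Cholesterol synthesis and heat shock were related most closely, with Pearson r 0.93 (two-sided exact permutation p 0.0125, adjusted 0.175), Spearman rho 0.89 (exact p 0.0333, adjusted 0.233) and r 0.91 without the 2 arrays farthest from the median.

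Cut into 2 clusters on measured genes, a number set beforehand, the 8 arrays split into arrays 2074 and 2076 and arrays 2194 to 2199, with a mean silhouette of 0.369. No other number of clusters was tried. Within the larger cluster, array 2195 correlated at 0.907 to 0.921 with the others, which correlated at 0.934 to 0.957 with each other. Arrays 2074 and 2076 correlated at 0.960 with each other and at 0.879 to 0.927 with the rest. Their scores lay above those of the other 6 arrays in 4 of 27 lists: cholesterol synthesis and uptake (0.24 and 0.37, against at most 0.23), survival and anti-apoptosis (0.33 and 0.43, against at most 0.16), follicle atresia-associated (0.53 and 0.11, against at most 0.10) and glycolysis and hypoxia (0.35 and 0.34, against at most 0.12). Arrays 2196 and 2199 were set apart in 6 lists, so this number is not peculiar to the pair. Arrays 2074 and 2076 also had the highest beta-actin 3' to 5' ratios (10.99 and 12.1, against 4.67 to 8.08 on the other 6).

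The spread of the immediate-early list was weighed against 2 technical explanations. The list stayed wide over arrays 2194 to 2199 alone (adjusted share 0.0025), where 7 lists were wide, and without array 2195 (0.0027). Neither test could decide, since the inner range already leaves out the lowest score, on array 2074 (-0.41), and the highest, on array 2076 (0.37). Its ends lay on arrays 2197 (-0.32) and 2198 (0.32), and array 2195 (0.22) set neither. Arrays 2074 and 2076 lay at opposite ends, so a shift shared by both did not set the range. Without the floor the call was lost (adjusted share 0.0958), where the median of random lists was 0.27 in place of 0.21 and the list itself had 0.59 in place of 0.64, and with genes required on all 8 arrays it stayed wide (0.57, adjusted share 0.013). Handling time before RNA extraction was not tested because no label gives it. No biological explanation could be tested.

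Cyp19a1, Inhba and Gja1, which joins granulosa cells through gap junctions, were lowest on arrays 2076 and 2196, which raised the hypothesis that granulosa markers are low on a shared pair. Only 3 of 13 markers had that pair lowest. Of random lists of like signal, 0.782 had as many on some pair (median 3), so a chance ordering may account for that count. The granulosa list score was also lowest on arrays 2196 (-0.43) and 2076 (-0.32), against -0.18 on the next array, 2199. The count of markers does not test this score. The list was not called wide with the primary settings (adjusted share 0.158) but was under 6 of 21 alternatives. Whether granulosa markers as a set are low on that pair therefore stays open.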
